A study of Oryctolagus cuniculus with 30 samples.

How the data were processed

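Epidermal RNA of 30 samples from female New Zealand White rabbits, a laboratory breed, was measured on 1-colour (Cy3) Agilent arrays of a custom rabbit design with 60-nucleotide probes, 1 sample per array. Per the labels' protocols, grids of incisions were made in the ear skin and kept under 1 layer of Tegaderm, a transparent adhesive film dressing, until the epidermis had closed 2 days after wounding, which is called day 0 here. From then on the right ear was left uncovered and the left ear was covered with 4 further layers. The epidermis was separated from the dermis with 0.5 M ammonium thiocyanate for 30 min, and 400 ng of total RNA entered the labelling. The groups were unwounded skin (2 arrays), wound at day 0 (6), uncovered wound at day 3 (6), covered wound at day 3 (5), uncovered wound at day 5 (6) and covered wound at day 5 (5). The labels do not tie arrays to animals, so p-values measure only the spread between these samples, and samples from the ears of the same animal may have entered both arms of a comparison.

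The deposited scanner files hold the intensity of each spot as read by Agilent's Feature Extraction, per the file headers. The processed signal used here had already been background-subtracted and detrended by that program, with a surrogate value for spots near background, and was not normalized between arrays, per the file headers. The same deposited files hold other columns of 0 or 1, flags for spots that are well above background, saturated or outlying. The deposited series table holds the authors' own intensity values on a linear scale, with 1 value per probe and nearly the same quantiles in every column. Its column medians lay between 286 and 293, and its log2 values correlated with the log2 scanner signals of the same arrays with r from 0.952 to 0.982, so the log scale and the direction are settled. The slope over bright probes was 0.728 to 0.932, and the background correction and any offset behind these values are not given in the sources used here. The submitters' processing notes name limma.

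Control spots and spots with an outlier flag were left out, the processed signal was put on the log2 scale, and spots of the same probe were averaged (20184 probes had 2 spots and 3185 had 1). A probe with 2 spots counted as well above background where both were. On 28 of the 30 arrays under 50% of the 23369 probes were well above background. The 75th percentile that was subtracted from each array was for this reason taken over the 7446 probes well above background on all arrays, and the same percentile over all probes was an alternative. The number of called probes had been computed under both scalings before this was settled, and the choice was then made on the detection rate. The median log2 change of all tested probes under this scaling was 0.13 and 0.17 for uncovered and covered wounds at day 3 against day 0, 0.47 and 0.33 at day 5 against day 0, and 0.31 and 0.26 at day 5 against unwounded skin. Changes in those comparisons are to be read relative to these medians, and the shares of higher and lower probes depend on the scaling and are given under both. The 12342 probes well above background on at least 2 arrays were tested. Levels are log2 units relative to this percentile. Where arrays of the dimmer group were at background, a floored fold is given. It compares the mean of the brighter group with a floored level of each array of the dimmer group. That level is the higher of the probe's own signal and the array's lowest signal among probes well above background. This lowest signal need not be the detection limit of the named probe, so a floored fold is not a lower bound.

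All 30 arrays and 6 groups entered a single limma 3.58.1 fit in R 4.3.3 (lmFit and eBayes, 2-sided, no block), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Overlaps of called probes were tested with Fisher's exact test and Benjamini-Hochberg adjustment over the 12 overlaps computed. This test takes probes as independent, which they are not, as some contigs carry several probes. The lists also come from a single fit with a shared spread per probe. The p-values of overlaps therefore do not measure the spread between samples. The number of arrays limits the precision. On simulated arrays with the spread of 11963 real probes and 200 changed probes, the fit for covered against uncovered at day 3 recovered 20.9% of 1.5-fold, 46.3% of 2-fold and 92.4% of 4-fold changes with 6 false calls. The same figures were 16.4%, 56.7% and 89.4% with 8 false calls at day 5, and 9.0%, 31.3% and 81.8% with 1 false call for the wound at day 0 against unwounded skin. The simulated noise was independent between probes and held no slide effect. Fewer probes were changed than were called in the real comparisons, so these figures describe the simulated setting and not the real fits.

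The array files describe all 23369 probes as unknown, give clone or contig names in place of genes, and carry no mapped position. None of these names matched the gene table of rabbit assembly mOryCun1.1 (0 of 23369). The gene lists and cell type marker lists chosen before the data were examined were not used here for this reason, and the rule for named genes, which asked for a gene symbol, named none. In its place, probes were ranked by the rest of that rule: past the threshold, well above background on every array of at least 1 of the compared groups, every array of the higher group above the mean of the lower group and the reverse. No more than the 2 largest rises and 2 largest falls are named, by probe and sequence, in the 3 main comparisons (covered against uncovered on each day, and the wound at day 0 against unwounded skin).

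The arrays lay on 11 slides scanned on 3 days. Of these, 10 slides held more than 1 group and slide 8 held a single array. Deviations from the group means correlated with a mean r of 0.29 between arrays of different groups on the same slide and -0.02 between arrays on different slides, so comparisons were repeated with slide as a fixed block, with slide as a random block, with scan day as a block and within slides. Other alternatives were normexp background correction of the mean signal (offset 50), quantile normalization, no filter on dim probes, a stricter filter, array weights, only the arrays compared, the authors' values, a 2-fold minimum, the replicate number as a block, and leaving out each array. The percentile over all probes, leaving out slide 6, the wound score and its alternatives, and the alternatives of the correlations were chosen after seeing the data.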

Results

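The series asks how hydration under an occlusive film changes gene expression in epidermis that has just closed over a wound. Expression was measured in separated rabbit ear epidermis on 30 arrays: unwounded skin (n = 2), wounds at closure (day 0, n = 6), and wounds left uncovered or covered with 4 further layers of film for 3 days (n = 6 and n = 5) or 5 days (n = 6 and n = 5). Between 39.7% and 50.4% of the 23369 probes were well above background per array. Within groups the arrays correlated across tested probes with r from 0.911 to 0.993. The first 2 principal components held 35.7% and 19.2% of the variance. All 6 arrays of the wound at day 0 had positive and all 6 arrays of uncovered wounds at day 5 negative values on component 1. On component 2 every covered array lay below every uncovered array of the same day, and the 2 arrays of slide 6 lay below all others.

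**Figure D1:**
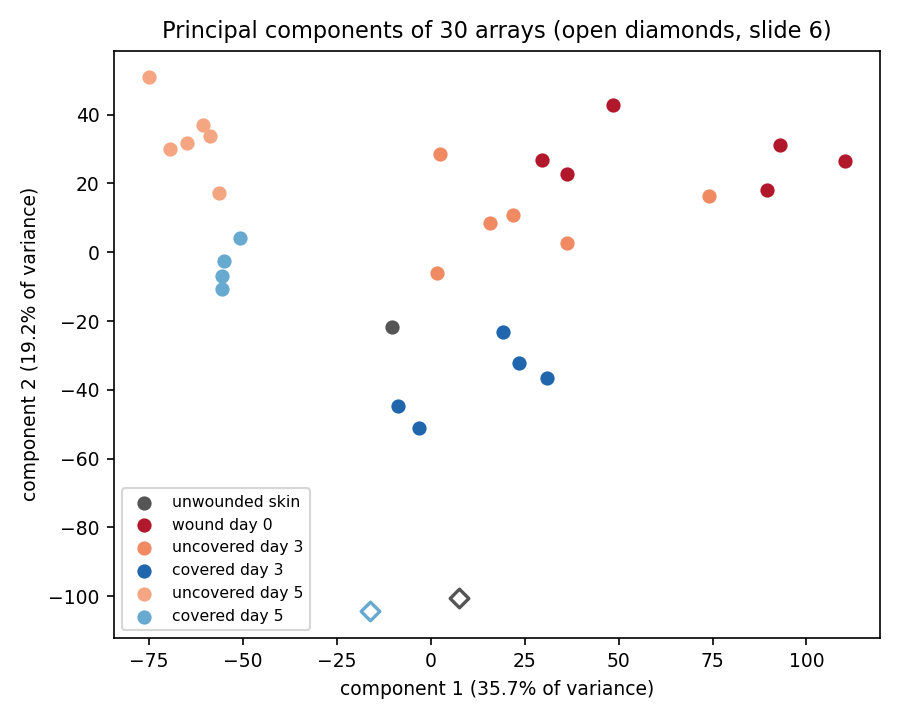
Principal components 1 and 2 of the 30 arrays over 11963 probes (arbitrary units, share of variance on each axis), with a point per array coloured by group. The 2 open diamonds, an unwounded and a covered day 5 array, share slide 6 and lie below all other arrays on component 2.

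Covered and uncovered wounds at day 3 were compared to see which transcripts respond to covering. The largest differences were falls. Probe UF_Ocu_AF_109724 (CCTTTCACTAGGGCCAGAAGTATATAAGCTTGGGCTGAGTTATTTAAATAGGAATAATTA) lay at 3.38 ± 0.46 (SD, n = 6) in uncovered and at -6.02 ± 1.85 (SD, n = 5) in covered wounds. That is a log2 change of -9.41 (SE 0.54, limma adjusted p = 7.86e-13), and the probe was well above background on 2 of the 5 covered arrays and all 6 uncovered arrays. With no covered array set below its lowest signal well above background, the difference was 508-fold. A second probe of the same contig, UF_Ocu_AF_109723 (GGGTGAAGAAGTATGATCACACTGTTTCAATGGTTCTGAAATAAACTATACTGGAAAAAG), changed by -9.26 (SE 0.54, limma adjusted p = 9.23e-13), or 523-fold in the same way, with 2 of 5 covered arrays well above background. Among the rises, the probe ranked first in this fit, though not in every alternative, was UF_Ocu_UN_119795 (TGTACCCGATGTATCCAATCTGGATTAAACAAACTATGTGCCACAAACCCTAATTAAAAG). It was well above background on 5 of 5 covered and 0 of 6 uncovered arrays. It was higher under cover (limma adjusted p = 0.000529), by 6.57-fold with no uncovered array set below its lowest signal well above background. UF_Ocu_AF_111877 (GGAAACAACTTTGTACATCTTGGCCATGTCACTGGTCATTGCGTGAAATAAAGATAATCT) showed the same detection and was higher (limma adjusted p = 4.72e-06), by 3.36-fold in the same way. Its lowest log2 change under an alternative was 1.13. Both rises lost their call with normexp background correction (adjusted p = 0.0961 and 0.255).

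In all, 2012 of 12342 probes differed at day 3, 1120 higher and 892 lower under cover. The lower probes moved further: their median log2 change was -1.04 against 0.75 for the higher probes, and among changes of at least 2-fold 471 probes were lower and 263 higher. This excess of large falls was also present with the percentile over all probes (469 lower, 267 higher), quantile normalization (447 and 291), normexp (283 and 71) and the authors' values (255 and 98). With slide as a fixed block 2265 probes were called. On slides 5, 9 and 11, which held a covered and an uncovered day 3 array, 99.2%, 97.3% and 96.6% of the probes called without that slide differed in the same direction. Normexp lowered the count to 814 (320 higher, 494 lower), and array weights raised it to 4187.

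At day 5 the same 2 probes fell furthest. UF_Ocu_AF_109724 changed by -9.40 (SE 0.54, limma adjusted p = 1.84e-12), from 2.73 ± 0.41 (SD, n = 6) in uncovered to -6.68 ± 0.82 (SD, n = 5) in covered wounds, where 1 of 5 arrays was well above background. UF_Ocu_AF_109723 changed by -9.26 (SE 0.54, limma adjusted p = 1.84e-12), with 3 of 5 covered arrays well above background. With no covered array set below its lowest signal well above background the falls were 493-fold and 451-fold. Rises were small by comparison. UF_Ocu_AF_101997 (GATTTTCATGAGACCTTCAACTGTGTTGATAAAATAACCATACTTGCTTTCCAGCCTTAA) rose by a log2 change of 1.58 (SE 0.29, limma adjusted p = 0.00069), or 3.0-fold, with 4 of 6 uncovered arrays well above background, and UF_Ocu_AF_104998 (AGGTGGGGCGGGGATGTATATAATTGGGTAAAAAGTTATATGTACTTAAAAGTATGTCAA) by 1.46 (SE 0.24, limma adjusted p = 0.000174), or 2.76-fold, with 5 of 6 uncovered arrays well above background. Both rises lost their call with normexp (adjusted p = 0.332 and 0.051).

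The day 5 comparison called 1696 probes, 884 higher and 812 lower under cover. Of the changes of at least 2-fold, 527 were lower and 79 higher, and the lower probes were also in excess with the percentile over all probes (471 and 163), quantile normalization (465 and 370), normexp (204 and 5) and the authors' values (239 and 13). The share of higher probes among all calls was 52.1%, and its direction is not settled. Quantile normalization gave 1593 higher and 784 lower, while lower probes were the majority with normexp background correction (162 higher, 284 lower), without the filter on dim probes (435 and 732), with scan day as a block (544 and 653) and without slide 6 (485 and 581). With slide as a fixed block 2055 probes were called (910 higher, 1145 lower), and on slides 1, 3 and 9 97.5%, 95.7% and 88.7% of the probes called without that slide went the same way. The count rested partly on single arrays: it fell to 914 without covered replicate 1, which lay on slide 6, to 1074 without covered replicate 4 and to 1079 without uncovered replicate 5.

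**Figure D2:**
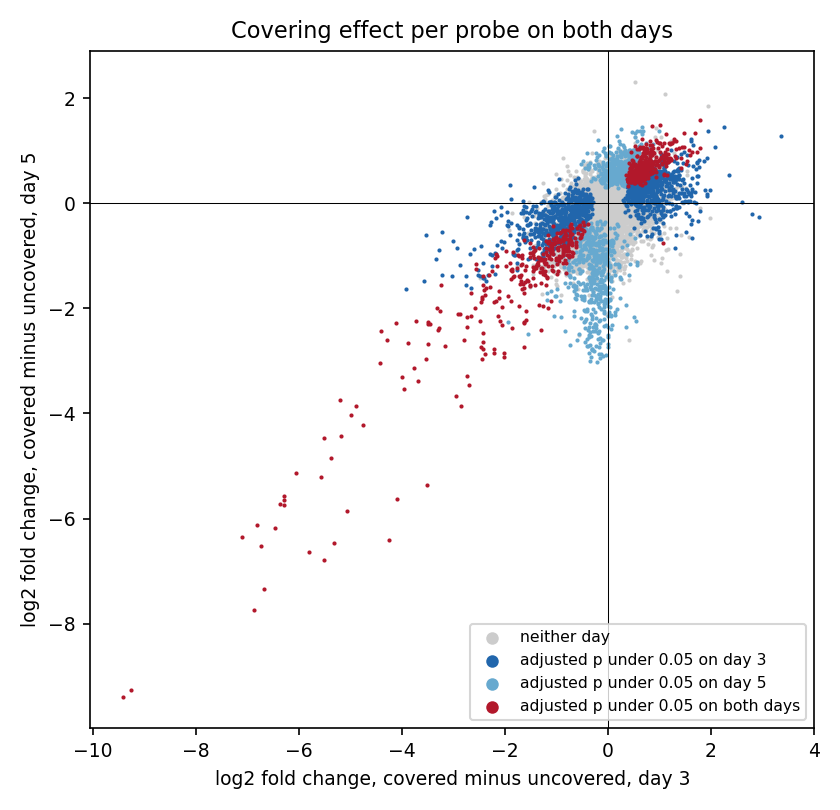
Log2 fold change of covered minus uncovered wounds at day 3 (horizontal) and day 5 (vertical), with a point per tested probe coloured by the day on which its adjusted p was under 0.05. The log2 changes correlate across 12342 probes with r = 0.645, and the fitted falls reach -9.41.

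The probes called on the 2 days overlapped. The p-values of these overlaps take probes as independent, which they are not. Of the 1120 higher at day 3 and the 884 higher at day 5, 344 were shared, where independent lists would share 80.2 (Fisher's exact test, adjusted p = 2.75e-143). Of the 892 and 812 lower probes 309 were shared, where independent lists would share 58.7 (Fisher's exact test, adjusted p = 1.41e-155). Of the probes called on both days 1 changed direction. Across probes, which are not independent replicates, the log2 changes of the 2 days correlated with r = 0.645. The difference between the days was itself called for 15 probes, 2 with a more positive and 13 with a more negative change at day 5. This count is not stable: it was 0 with normexp (limma, 661 at an unadjusted p under 0.05), 100 with quantile normalization and 390 with array weights, and ran from 5 to 41 with 1 array left out. UF_Ocu_AF_111877 was among the 13 with a more negative change (limma adjusted p = 0.00837 for the difference). It was higher under cover at day 3, by 3.36-fold with no uncovered array set below its lowest signal well above background. At day 5, where 2 of 6 uncovered and 1 of 5 covered arrays were well above background, covering did not pass the threshold (limma adjusted p = 0.674).

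The wound at day 0 was compared with unwounded skin. The wounds had been under 1 layer of film until then, so this comparison may mix wounding with that cover. UF_Ocu_AF_101829 (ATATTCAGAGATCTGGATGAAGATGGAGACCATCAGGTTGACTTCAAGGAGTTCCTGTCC) rose most in this fit, from -6.37 ± 1.41 (SD, n = 2) to 3.52 ± 0.55 (SD, n = 6). That is a log2 change of 9.89 (SE 1.07, limma adjusted p = 1.52e-07), with 1 of the 2 unwounded arrays well above background. With no unwounded array set below its lowest signal well above background the rise was 841-fold. UF_Ocu_AF_101828 of the same contig (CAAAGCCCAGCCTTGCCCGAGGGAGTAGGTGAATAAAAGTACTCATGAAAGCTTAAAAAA) rose by 8.94 (SE 0.92, limma adjusted p = 6.79e-08). Both stayed high in uncovered wounds and not in covered wounds: UF_Ocu_AF_101829 lay at 1.69 ± 0.86 (SD, n = 6) uncovered and -5.17 ± 2.35 (SD, n = 5) covered at day 3 (log2 change -6.86, SE 0.79, limma adjusted p = 5.95e-07, 3 of 5 covered arrays well above background), and at 0.96 ± 0.63 (SD, n = 6) and -6.79 ± 1.91 (SD, n = 5) at day 5, where 1 of 5 covered arrays was well above background. With covered arrays held at that lowest signal its falls were 90.9-fold and 146-fold. UF_Ocu_AF_109724, at background on both unwounded arrays, was higher in the wound (limma adjusted p = 1.05e-06), by 54.1-fold with unwounded arrays held in the same way. The largest falls in this fit were log2 changes of -9.45 (SE 1.69, limma adjusted p = 8.84e-05) for UF_Ocu_AF_107910 (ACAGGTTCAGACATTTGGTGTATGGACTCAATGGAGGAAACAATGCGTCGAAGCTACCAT) and -8.64 (SE 1.78, limma adjusted p = 0.000393) for UF_Ocu_AF_103486 (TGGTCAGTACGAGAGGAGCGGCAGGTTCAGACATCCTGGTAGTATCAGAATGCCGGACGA). With no wound array set below its lowest signal well above background the falls were 255-fold and 198-fold. The log2 change of UF_Ocu_AF_107910 was -6.86 with slide as a fixed block, -7.51 without unwounded replicate 2 and -11.39 without unwounded replicate 1, and that of UF_Ocu_AF_103486 -6.85, -7.40 and -9.87. Both varied widely within groups: UF_Ocu_AF_107910 lay at 2.50 ± 2.74 (SD, n = 2) in unwounded skin and -6.95 ± 2.95 (SD, n = 6) at day 0, with 2 of 6 wound arrays well above background, and each of these 2 probes was saturated on 1 array.

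**Figure D3:**
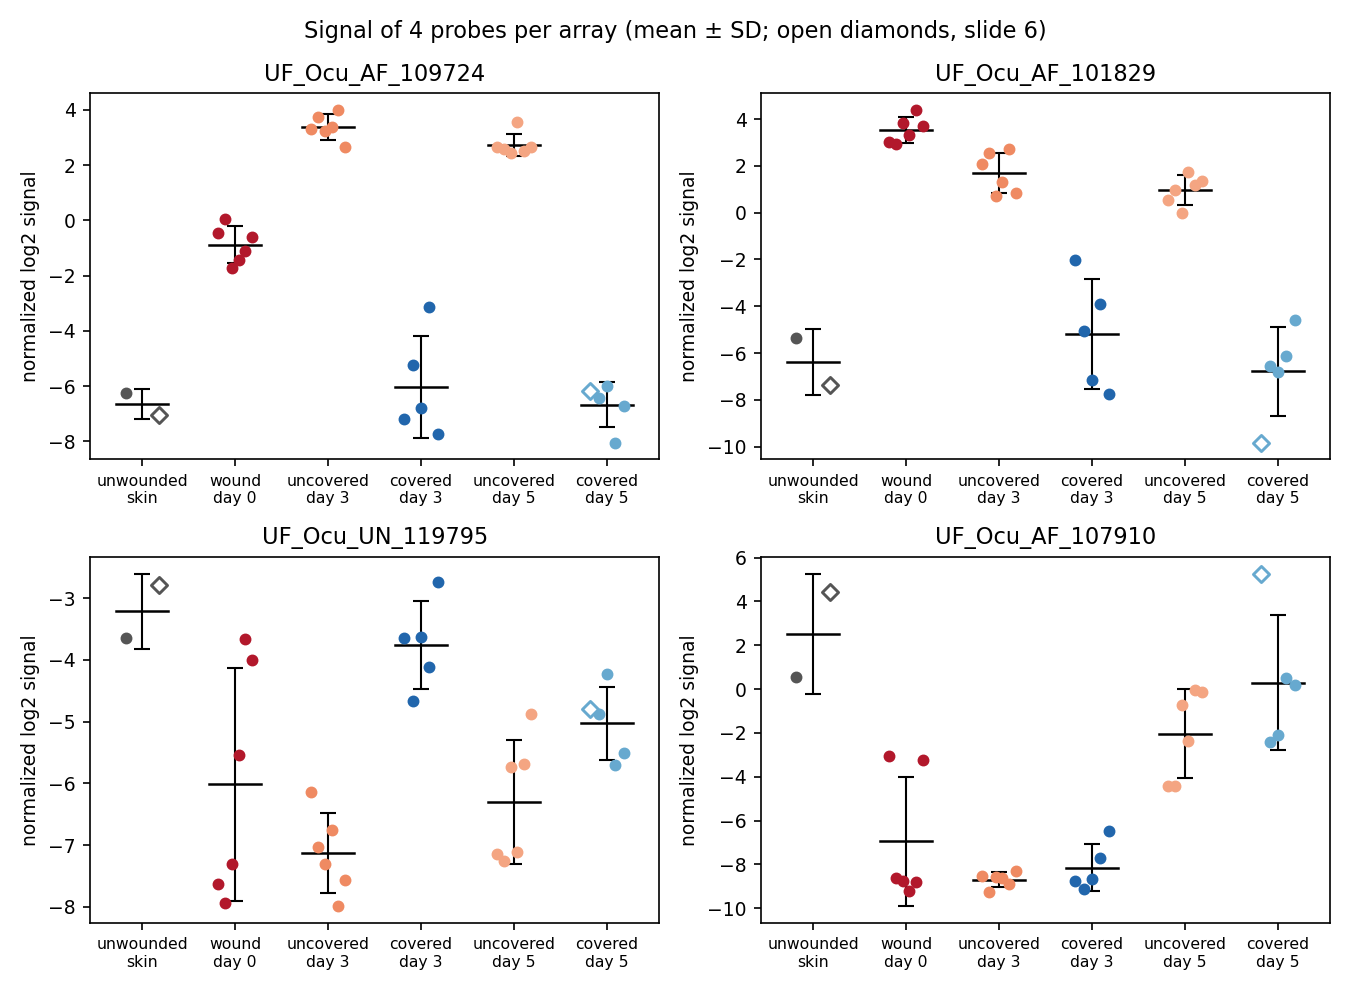
Normalized log2 signal (vertical) of 4 probes on each array by group, with bars for the mean and SD and open diamonds for the slide 6 arrays. UF_Ocu_AF_109724 and UF_Ocu_AF_101829 are high at day 0 and in uncovered wounds and low in covered wounds and unwounded skin.

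The wound comparison called 4598 probes, 2107 higher and 2491 lower. The balance turned with the percentile over all probes (2355 higher, 2169 lower), quantile normalization (2341 and 2255) and normexp (1732 and 1132), so its direction is not settled. Unwounded skin had 2 arrays, and without its replicate 2, on slide 6, 2575 probes were called, the remaining array being assumed to vary like the other groups. With slide as a fixed block 3911 probes were called. Each slide held at most 1 of the 2 groups, so no value within a slide can be given.

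The wound calls overlapped with the covering calls in opposite directions. No array is shared between these comparisons, but they share a fit, and the p-values of the overlaps take probes as independent, which they are not. Of the 892 probes lower under cover at day 3, 481 were higher in the wound at day 0 than in unwounded skin, against 152 for independent lists (Fisher's exact test, adjusted p = 3.98e-152). Of the 1120 probes higher under cover, 661 were lower in the wound, against 226 (Fisher's exact test, adjusted p = 3.18e-200). The same directions of change were shared by 29 and 57 probes, fewer than the 191 and 180 of independent lists. At day 5, 251 probes higher in the wound were lower under cover, against 139, and 243 lower in the wound were higher under cover, against 178 (Fisher's exact test, adjusted p = 1.07e-23 and 6.81e-08). Of the probes with the same direction, 142 were higher in both, near the 151 of independent lists (Fisher's exact test, adjusted p = 0.43), and 56 were lower in both, fewer than 164 (adjusted p = 2.73e-27). The day 5 overlap in opposite directions, 494 in all, was 318 without covered replicate 1, 262 without slide 6 and 316 with scan day as a block. Across probes the correlation of log2 changes with wounding and with covering was -0.513 at day 3 and -0.289 at day 5, and -0.412 and -0.136 with slide as a fixed block. The day 5 value rested largely on unwounded replicate 2, on slide 6: it was -0.109 without that array, -0.152 without slide 6 and -0.111 with scan day as a block.

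A wound score, chosen after seeing the data, was computed for each array as the mean log2 level of the 2107 probes higher in the wound minus that of the 2491 lower probes, each centred over all arrays. It was 1.67 ± 0.22 (SD, n = 6) at day 0 and -1.25 ± 0.47 (SD, n = 2) in unwounded skin, the groups that define it. At day 3 it was 0.23 ± 0.44 (SD, n = 6) in uncovered and -0.58 ± 0.15 (SD, n = 5) in covered wounds, a difference of -0.81 with each covered array below each uncovered array (exact 2-sided permutation p = 0.00217, the smallest that 462 splits can give, adjusted p = 0.00433 over 6 tests). At day 5 it was -0.41 ± 0.07 (SD, n = 6) and -0.70 ± 0.26 (SD, n = 5), a difference of -0.29 (exact 2-sided permutation p = 0.00649, adjusted p = 0.00779), with the covered array higher in 6.67% of pairs. Single arrays moved the day 5 difference to -0.18 (without covered replicate 1, on slide 6) and to -0.50 (without unwounded replicate 1). Covered minus uncovered was -0.36, -0.54 and -1.46 on slides 5, 9 and 11 at day 3, and -0.28, -0.10 and -0.31 on slides 1, 3 and 9 at day 5. The score is built from the wound calls. The sign of its day 3 difference follows from the correlation of changes with wounding and with covering given above. The day 3 p-value is therefore not separate evidence of that pattern.

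**Figure D4:**
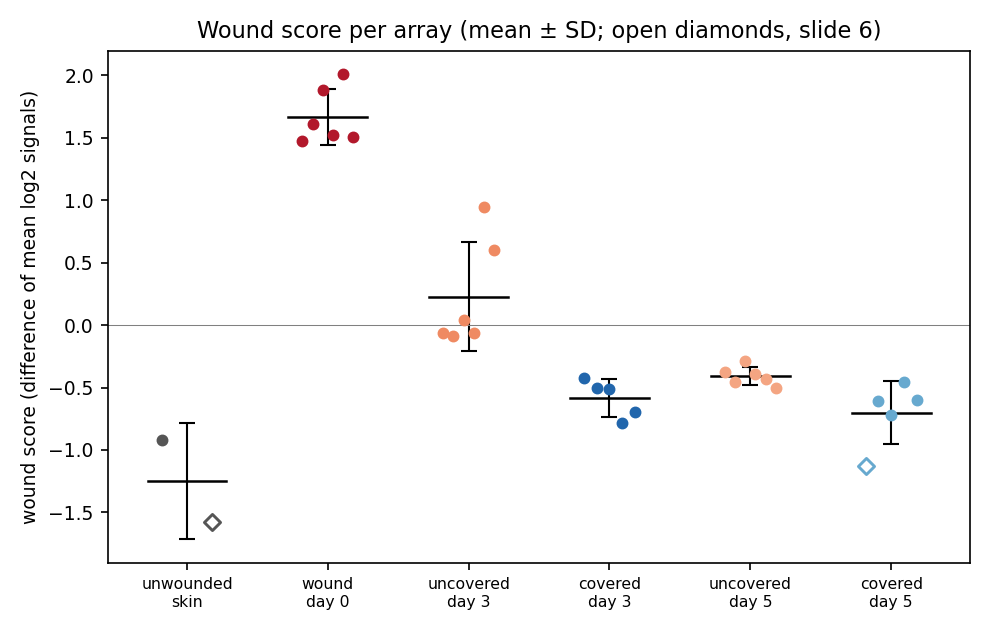
Wound score of each array (difference of mean log2 signals, vertical) by group, with bars for the mean and SD and open diamonds for slide 6; the score was chosen after seeing the data. All 5 covered arrays lie below all 6 uncovered arrays at day 3.

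The later wounds were compared with day 0 to follow each arm over time. Wounds at day 0 had been under 1 layer of film, so these differences mix time with a change of cover. UF_Ocu_AF_109724 rose further without cover, by 4.26 (SE 0.51, limma adjusted p = 3.72e-07) to day 3, and was lower under cover (limma adjusted p = 1.44e-08), where 2 of 5 arrays were well above background, by 26.5-fold with no covered array set below its lowest signal well above background. UF_Ocu_AF_101829 was lower under cover (limma adjusted p = 1.59e-09), with 3 of 5 arrays well above background, by 323-fold in the same way, and its difference without cover, -1.83 (SE 0.76, limma adjusted p = 0.0614), did not pass the threshold. UF_Ocu_AF_107910 was well above background on 2 of 6 arrays at day 0, and by day 5 on 6 of 6 uncovered and 5 of 5 covered arrays. At day 3, 4402 probes differed from day 0 in uncovered (2535 higher, 1867 lower) and 5495 in covered wounds (3250 higher, 2245 lower). At day 5 the counts were 8081 (5442 higher, 2639 lower) and 6925 (4701 higher, 2224 lower). The balance depends on the scaling. With the percentile over all probes the splits were 1781 higher and 2427 lower, 2509 and 2737, 3553 and 3871, and 3265 and 3176 in the same order, and quantile normalization gave 1927 and 2284, 2730 and 2618, 3349 and 3820, and 3362 and 3128. With slide as a fixed block the 4 counts were 5067, 5832, 8481 and 7157, and within the slides that held both groups 82.1% to 97.7% of the probes called without that slide went the same way.

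The wounds at day 5 were set against unwounded skin to see what difference was left. UF_Ocu_AF_109724 was higher in uncovered wounds (limma adjusted p = 1.42e-09), by 658-fold with no unwounded array set below its lowest signal well above background. It was at background on both unwounded and on all but 1 of the covered arrays, so this probe could not measure a remaining difference in covered wounds. For UF_Ocu_AF_109723 of the same contig, well above background on 3 of 5 covered and 1 of 2 unwounded arrays, that difference was -0.04 (SE 0.74, limma adjusted p = 0.979), also near the floor. UF_Ocu_AF_101829, well above background on 1 of the 2 unwounded arrays, was higher in uncovered wounds (limma adjusted p = 2.09e-05), by 142-fold with no unwounded array set below its lowest signal well above background. In covered wounds it was well above background on 1 of 5 arrays. UF_Ocu_AF_101828 of the same contig, well above background on all 5 covered and both unwounded arrays, lay at -4.65 ± 1.57 (SD, n = 5) in covered wounds and -4.43 ± 1.24 (SD, n = 2) in unwounded skin, a difference of -0.22 (SE 0.94, limma adjusted p = 0.9) that did not pass the threshold. In all, 3985 probes differed in uncovered wounds (2707 higher, 1278 lower) and 972 in covered wounds (815 higher, 157 lower). With the percentile over all probes the splits were 1697 and 2214, and 432 and 239. Both counts rest on 2 unwounded arrays, 1 of which shares slide 6 with covered replicate 1: without that covered array 2564 probes differed in covered wounds, and without unwounded replicate 2 the counts were 872 uncovered and 279 covered. With slide as a fixed block they were 1998 and 870. On slide 5, 91.0% of the uncovered calls made without it went the same way, and on slide 6 92.8% of the covered calls did.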

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

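The 3 patterns weighed here, and the tests of a shared slide effect, were chosen after the data were seen, and so were the rule that a bound must be passed by more than the spread of its value and the fits set beside it for the counts at day 5. The splits of the labels were drawn in 2 sets of 100, and both are given. Of 60 groups of arrays tested for an array far from the others, 5 held one, and chance flags about 1 in 20.

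The level of UF_Ocu_AF_111877 was -7.825 in wound day 0 replicate 4 and -8.966 to -8.668 in the other arrays of its group, all at background. In uncovered day 5 replicate 4 the level of UF_Ocu_AF_109724 was 3.546 (others 2.419 to 2.66) and that of UF_Ocu_AF_109723 3.454 (others 2.592 to 2.763). In covered day 5 replicate 4 the level of UF_Ocu_AF_109723 was -8.239 (others -6.219 to -5.689). The share of probes well above background was 45.145% in uncovered day 3 replicate 2 and 41.149% to 41.683% in the other arrays of its group.

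The effect of covering differed between day 3 and day 5 for 15 probes by limma's test of the difference (1502 at an unadjusted p under 0.05). Over complete probes 3 of 100 reassignments of the day labels within each treatment, the real one with 14 probes included, gave as many in the first draw (highest other 4161) and 2 of 100 in the second (highest other 26). In the reassignment with 4161 the labels of 10 uncovered but 2 covered arrays were changed, so the change from day 3 to day 5 itself entered the difference. So high a count points to this structure of the samples. It rests on a single reassignment and did not recur in the second draw.

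For the other comparisons of groups of at least 3 arrays, 1 of 100 splits, the real one, gave as many called probes in either draw. That is the smallest share that 100 splits can give. It argues against chance among the splits drawn but does not exclude it. The splits took the arrays as exchangeable, and the labels do not tie arrays to animals. Covered against uncovered wounds gave 2002 probes at day 3, where the highest other split gave 401 in the first and 1877 in the second draw. The split with 1877 exchanged the labels of 10 of the 11 arrays and so nearly mirrors the real one. At day 5 the real split gave 1662 and the highest other 826 in both draws, again with 10 of the 11 labels exchanged. Against day 0, the real split gave 4334 for uncovered day 3 (highest other 3528 and 3390), 5388 for covered day 3 (4657 and 2577), 7815 for uncovered day 5 (5603 in both draws) and 6695 for covered day 5 (5825 and 5185). The highest other splits against day 0 exchanged the labels of 2, 8 or 10 arrays. Those with 2 lay near the real split and those with 10 near its mirror. The median over the other splits was 0 called probes in each comparison and draw.

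The 2 arrays of slide 6, unwounded replicate 2 and covered day 5 replicate 1, stood apart from the other arrays of their groups. Their deviations correlated across probes with r = 0.724, above the highest r of 0.62 between arrays of different slides and groups, which goes with a shared slide effect. With 2 unwounded arrays the deviation of replicate 1 is the mirror of that of replicate 2 (r = -0.724). Set against the mean of the other groups, replicate 2 correlated with the deviation of the covered array with r = 0.718 and replicate 1 with r = 0.0255, so the likeness lies with replicate 2. The 2 arrays are also the only ones of their scan day, and the labels do not say whether they share an animal, so slide, scan day and animal cannot be separated. The covered array had 176 and the unwounded array 23 saturated probes, against at most 4 on any other array. Their 75th percentiles of the processed signal, 1510 and 1346, were the highest. They had 595 and 257 outlier spots, but covered day 5 replicate 4 on slide 2 had 267. The cause of these values was not tested. GC content explained an R squared of 0.162 of the mean deviation (16.2%, 95% bootstrap interval 15.0% to 17.5%) and signal level 0.0934 (9.34%, 8.47% to 10.4%). Both may contribute, and neither came near the 50% set for a main cause. No biological explanation was tested, since the 2 arrays belong to different groups.

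Changes with covering at day 3 ran opposite to changes with wounding (r = -0.513 across probes, which are not independent replicates). Without slide 6 the correlation was -0.502, and it was at most -0.429 in 47 fits that left out slide 6 and a further array or 1 array. Its highest value over all 31 alternatives, which include the fits with slide as a block, was -0.375. These values argue against slide 6 as the main source, though the fits without slide 6 keep 1 unwounded array. After GC content and signal level were taken out the correlation was -0.512, which argues against probe properties. A candidate explanation is that covering shifts wound-changed transcripts towards unwounded skin. The lower wound score of covered wounds (exact permutation p = 0.00217) does not test it, since the score is built from the wound calls and its sign follows from the correlation, so the explanation stays open. A different mix of cells in the separated epidermis was not tested, as the probes carry no gene names.

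At day 5 fewer probes differed from unwounded skin in covered (972) than in uncovered wounds (3985); the 2 counts share the unwounded arrays, and the direct test of covered against uncovered called 1696. Without slide 6 the covered count was 24.8% of the uncovered count (309 and 1245, and 19.8% to 28.3% over 10 fits without a further array), below the bound set for slide 6 as the source. That bound assumed that the fit without slide 6 compares like with like, but it keeps 1 unwounded array and lowers both counts. Other fits that adjust for slide 6 gave 43.5% with slide as a fixed block (870 and 1998), 35.0% with slide as a random block (1294 and 3702) and 47.2% with scan day as a block (811 and 1719), so slide 6 stays open as a part of the source. Leaving out 1 uncovered array to even the group sizes, the uncovered count was at least 3.39 times the covered count, which argues against group size. The ratio depends on single arrays: it was 1.55 without covered replicate 1 (2564 covered) and 2.04 without unwounded replicate 1 (2031 covered), and 3.12 without unwounded replicate 2 (279 covered, 872 uncovered). That covered wounds may lie nearer to unwounded skin at day 5 is an untested hypothesis resting on 2 unwounded arrays, 1 of them on slide 6.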

How the results depend on the processing

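The percentile over all probes, leaving out slide 6, and the wound score and correlations with their alternatives were chosen after seeing the data. The gene list tests, the averaging of probes per gene and the cell type markers were not run, as no probe has a gene name. No change of a named probe, correlation or wound score reversed. Single called probes did take the opposite sign, such as 473 of 6925 with normexp (covered day 5 against day 0) and 369 of 8081 with quantile normalization (uncovered day 5 against day 0). The balance of covering calls at day 3 turned from 1120 higher and 892 lower to 320 and 494 with normexp and to 757 and 799 with only the arrays compared. Of the named probes' changes, 272 of 276 values under alternatives kept their direction and call. These probes were named as the largest changes of the main fit, so this share was largely fixed in advance. The other 4 values, which cover every rise named for covering, fell short of the threshold with normexp: UF_Ocu_UN_119795 (log2 change 1.53), UF_Ocu_AF_111877 (1.25), UF_Ocu_AF_101997 (0.89) and UF_Ocu_AF_104998 (0.94). Counts of called probes stayed within 1.5 times the reported count in 95 of 140 values under other alternatives and 94 of 113 with 1 array left out. The same held for 26 of 36 and 58 of 60 overlaps. Correlations moved by less than the limit in 30 of 36 and 59 of 60 values, and wound scores kept their direction and call in 16 of 16 and 38 of 38. The wound score was not computed with slide, scan day or replicate number as a block. The correlation of the changes with wounding and with covering at day 5 moved most, from -0.289 to -0.109 without unwounded replicate 2. Under 50% of probes were well above background on 28 of 30 arrays, which limits what can be seen of dim transcripts. The cause of a shift was not tested unless stated.

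With normexp, covered against uncovered wounds gave 814 probes at day 3 and 446 at day 5, and limma called 0 for the difference between days (661 at an unadjusted p under 0.05). It gave 2864 for the wound, against day 0 2432 (uncovered day 3), 3434 (covered day 3), 4780 (uncovered day 5) and 4165 (covered day 5), and against unwounded skin 1597 (uncovered day 5) and 107 (covered day 5). The overlaps were 222 between days, and 518 and 203 of wound calls with covering calls at day 3 and day 5. A 2-fold minimum, which by construction calls fewer probes, gave 734 and 606 for covering at day 3 and day 5, 1834, 2880, 4716 and 3988 against day 0 in the same order, and 2604 for uncovered day 5 against unwounded skin. Array weights gave 4187 and 2636 for covering, 390 for the difference between days, 2610 for the wound, 1679 and 273 for uncovered and covered day 5 against unwounded skin, and an overlap of 1608 between days.

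With no filter on dim probes, uncovered day 5 against day 0 gave 18286 probes, covered day 5 against unwounded skin 644, the difference between days 8, and the overlaps 361 between days and 745 and 278 with the wound. Quantile normalization gave 100 for the difference between days and 528 for covered day 5 against unwounded skin. The authors' values gave 197 and 613, and the percentile over all probes 25 for the difference between days. With only the arrays compared, and so fewer samples, the difference between days gave 7, the wound 2636 and covered day 5 against unwounded skin 305.

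With slide as a fixed block the difference between days gave 36 and uncovered day 5 against unwounded skin 1998, with slide as a random block the difference between days 109 and the overlap between days 1060. With scan day as a block the difference between days gave 60, uncovered day 5 against unwounded skin 1719 and the overlap of the wound with covering at day 5 316. Over all group pairs the mean r of deviations was 0.0039 for the same replicate number and 0.0012 otherwise. Such means cannot exclude paired ears. The replicate block gave 1812 and 1377 for covering at day 3 and day 5, and 8 for the difference between days. Without slide 6, covering at day 5 gave 1066, the difference between days 50, the wound 3033, uncovered and covered day 5 against unwounded skin 1245 and 309, and the overlap of the wound with covering at day 5 262.

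With 1 array left out, the wound gave 2575 (without unwounded replicate 2) to 4722 probes, uncovered day 5 against unwounded skin 872 (without unwounded replicate 2) to 4144, and covered day 5 against unwounded skin 279 (without unwounded replicate 2) to 2564 (without covered day 5 replicate 1), with 2031 without unwounded replicate 1. The array left in a group of 1 is assumed to vary like the other groups. Covering gave 1442 to 2177 at day 3, and at day 5 914 (without covered replicate 1) to 2186, with 1074 without covered replicate 4 and 1079 without uncovered replicate 5. Against day 0 the ranges were 3901 to 4707 (uncovered day 3), 5079 to 5423 (covered day 3), 7601 to 8096 (uncovered day 5) and 6461 to 7450 (covered day 5). The overlap between days was 428 (without covered day 5 replicate 4) to 717, and those with the wound 882 to 1224 at day 3 and 318 (without covered day 5 replicate 1) to 585 at day 5. The difference between days gave 5 to 41. It was 5 without covered day 3 replicate 1 or 5 or uncovered day 5 replicate 5 or 6, 6 without covered day 3 replicate 3 or uncovered day 3 replicate 5, 7 without uncovered day 3 replicate 2, 9 without covered day 3 replicate 2, 24 and 25 without covered day 5 replicates 1 and 3, and 41 without uncovered day 3 replicate 4.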

Other observations

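The tests of the wound score were chosen after the data were seen. Its parts were tested separately, and no test compared them with each other. Unlike the score itself, each part shifts with the scaling of an array, and the parts were not computed under other scalings. The mean level of probes raised in the wound was lower in covered than in uncovered wounds by a log2 difference of -0.46 at day 3 and -0.24 at day 5, with 0% of pairs higher under cover on either day (exact permutation p = 0.00217 for each, adjusted p = 0.00433). The mean level of probes lowered in the wound was higher under cover by 0.36 at day 3 (exact permutation p = 0.00649, adjusted p = 0.00779), and at day 5 the difference of 0.06 did not pass the threshold (exact permutation p = 0.221). The difference between days of the covering effect on the score was 0.52 (permutation p = 0.0706 over 232848 reassignments). The day labels were reassigned within each treatment, so the change from day 3 to day 5 itself entered the reassigned values. This p-value therefore cannot decide whether the covering effect differs between days.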
